A study of Mus musculus with 12 samples.

How the data were processed

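RNA was measured in microglia, the resident macrophages of the brain, taken from 2 regions of mice of 2 genotypes. The regions were the cortex and the ventricular-subventricular zone (V-SVZ), the lining of the lateral ventricle in which new neurons are born in the adult. The genotypes were wild type (WT, C57BL/6) and Jedi-1 knockout (JKO), in which Pear1, the gene of the engulfment receptor Jedi-1, carries a tm1a allele, per the labels' protocols. An allele of this design traps the transcript inside the gene, so that some exons can still be read. Per the labels' protocols, microdissected tissue was digested with papain, cells were captured on CD11b magnetic beads, and poly-A libraries were sequenced with paired-end reads on a NovaSeq. CD11b is carried by other myeloid cells too, and bead capture can bring along cells and RNA of other types.

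The submitters' processing notes name Trim Galore 0.6.7, STAR, TopHat2 2.0.11 and Cuffdiff 2.1.1 and the build GRCm38 (mm10), without their order or role. The column names carry HTSeq, a read counter, per the file headers. The setting for strand and the annotation release were not given in the sources used here. The signal values that the authors deposited are gene counts divided by 1 size factor per library, which the names of the tables call DESeq-normalized, and each of the 4 comparisons was normalized in its own table. Dividing each column by its smallest step gave whole reads for 100% of the values within a tolerance of 0.01, and each library's reads were identical in both tables that hold it. The authors also deposited, for each comparison, a log2 fold change per gene from DESeq, per the file headers. A p-value and an adjusted p-value per gene stand beside it in the tables the authors deposited. Size-factor scaling sets the median gene of the compared libraries level, so a broad change in the mix of cells appears as opposite changes in the genes of each cell type.

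The series has 12 samples in 4 groups of 3. The labels describe 3 of them as outliers (JKO V-SVZ 1, WT cortex 3 and WT V-SVZ 3), and no column of the tables used here holds them. The 9 libraries analysed here were WT cortex 1 and 2, WT V-SVZ 1 and 2, JKO cortex 1, 2 and 3, and JKO V-SVZ 2 and 3. Replicate numbers follow the order of the samples and are not used as pairs, as the labels tie no samples to an animal. The sample titles start with 7814 in 3 libraries (WT cortex 1, WT V-SVZ 1 and JKO cortex 1) and with 8156 in the other 6, and the labels do not say what this prefix stands for. Libraries of prefix 7814 were the deeper ones. The labels do not say that the samples came from separate animals, so the p-values measure the spread between these samples. The tables hold 32285 genes, of which 24132 have a symbol in the files. A symbol was added for 8082 more by gene identifier from GENCODE M21, which is on GRCm38 and holds 32158 of the identifiers, and positions are from the same annotation.

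The 4 comparisons and their interaction were fixed, with their tests and gene lists, before the data were examined. Each comparison was fitted within its own table with limma 3.58.1 (R 4.3.3) on log2(normalized count + 1), with a mean-variance trend and robust moderation, for genes with a mean of at least 10. Fold changes on this scale understate the change of low genes. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The residual degrees of freedom were 2 for the WT region and V-SVZ genotype comparisons and 3 for the JKO region and cortex genotype comparisons. The region by genotype interaction was fitted over all 9 libraries, with WT values from the WT region table, JKO values from the JKO region table, and the difference centred on its median gene. Levels are given as CPM, the recovered reads scaled to an equal total in every library, and, for lists, as the mean of log2(CPM + 0.1).

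Gene lists were compared with all other tested genes by camera of limma, with a preset correlation of 0.01 between genes, in 29 lists with at least 5 tested genes, and again with an estimated correlation. For microglia and their functions the lists were homeostatic microglia, disease- and development-associated microglia, apoptotic cell engulfment, lysosome, inflammatory cytokines and chemokines, interferon response, antigen presentation, cell cycle, growth and neurotrophic factors, unfolded protein and integrated stress response, lipid and cholesterol handling, and glycolysis. For other cells they were border-associated macrophage, monocyte, neutrophil, lymphocyte, neural stem cell and astrocyte, transit-amplifying progenitor and neuroblast (called neuroblast here), cortical neuron, oligodendrocyte lineage, ependymal, choroid plexus, endothelial, mural cell and fibroblast, and erythroid. As checks of quality there were dissociation and immediate early response (called immediate early here) and sex-linked genes. The remaining lists were genes that differ between the C57BL/6J and C57BL/6N strains, and neighbours of Pear1 on chromosome 3. Some genes stand on more than 1 list, such as P2ry12 and Mertk on the homeostatic and engulfment lists.

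The genes named in the text were Pear1, the 10 called genes with the largest change in each direction among those with a mean of at least 50, no overlap between the groups' libraries and an assigned name, up to 4 members per list with the smallest p, and Il1b, Igf1, P2ry12, Tmem119, Spp1, Apoe, Mrc1, Nnt and Xist. Where fewer than 10 genes were called, the 5 with the smallest p in each direction were named as not called. Not every gene that meets this rule is described in the text. The alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, quantile normalization, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, the title prefix as a covariate, an estimated correlation for the lists, and leaving out each library in turn. A scaling on the homeostatic list, a fit of all 9 libraries together, a fit of prefix 8156 alone and list tests of the interaction were chosen after seeing the data. The homeostatic scaling sets the mean of the homeostatic list level between libraries, so this list's own values on it are fixed in advance. It moves the log2 fold change of every gene in a comparison by the same amount. A change of sign on it is therefore no separate test, and camera was not run on this scale. The scaling also carries the spread of the homeostatic list between libraries into every gene, so a lost call need not mean a smaller change.

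The gene tests, the list test and the interaction step were tried on simulated counts drawn from the real means and depths, with 200 genes changed. At 4-fold, limma recovered 75.5% of them in the WT region comparison (18717 genes), 74% in the JKO region comparison (16992 genes), 74% in the cortex genotype comparison (17650 genes) and 73% in the V-SVZ genotype comparison (17770 genes). False calls made up 7.36%, 6.33%, 7.50% and 8.18% of those calls in the same order. At 2-fold the recovered shares were 35.5%, 7.50%, 26.5% and 2% on 18718, 16972, 17618 and 17772 genes, with 22.8%, 6.25%, 7.02% and 20% false calls in the same order. At 4-fold the interaction step recovered 50.5% with 5.61% false calls on 18070 genes. DESeq2 recovered more, and its false calls lay between 22.5% (V-SVZ genotype, 4-fold) and 44.2% (cortex genotype, 2-fold). In these simulations few genes changed and genes varied independently. The shares of false calls therefore do not carry over to the real libraries. The homeostatic scaling and the tests of explanations were not simulated.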

Results

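Poly-A RNA of CD11b-selected brain cells was compared by region and by genotype in 9 mouse libraries, to ask how microglia of the V-SVZ differ from those of the cortex and how each changes without Jedi-1. There were 2 WT cortex, 2 WT V-SVZ, 3 JKO cortex and 2 JKO V-SVZ libraries, and WT cortex served as the control group of the series. WT cortex libraries held 274418093 and 42122424 reads, and WT V-SVZ libraries 278088368 and 34052503 reads. JKO cortex libraries held 210887180, 28642516 and 36232444 reads, and JKO V-SVZ libraries 39980361 and 41581763 reads. The 3 libraries above 200 M reads were those with title prefix 7814. The most abundant gene, Gm26917, a predicted RNA with similarity to ribosomal RNA, took 6.30% to 11.6% of the reads, and mitochondrial genes took 0.469% to 0.768%. Across genes, Spearman's rho was 0.981 to 0.991 for the 6 pairs of libraries within a group and 0.923 to 0.988 for the 30 pairs between groups.

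Pear1 was low in every library labelled JKO. Pear1 (ENSMUSG00000028073), the gene that the knockout allele targets, lies on the minus strand of chromosome 3 at 87747890 to 87824306 (GRCm38). Its counts are per gene, without a split by exon. WT cortex libraries held 110 and 83.2 CPM (mean 96.4 ± 18.6, SD, n = 2) and WT V-SVZ libraries 44.8 and 40.4 CPM (42.6 ± 3.10, SD, n = 2). JKO cortex libraries held 7.92, 5.17 and 3.75 CPM (5.61 ± 2.12, SD, n = 3) and JKO V-SVZ libraries 2.40 and 2.33 CPM (2.37 ± 0.0484, SD, n = 2). JKO levels were thus 5.83% of WT in cortex and 5.56% in V-SVZ. The log2 fold change of JKO against WT was −3.88 ± 0.26 (SE) in V-SVZ, where Pear1 fell (limma, adjusted p = 0.0388), and −4.03 ± 0.30 in cortex, where it was not called (adjusted p = 0.0751). Without WT V-SVZ 2 the V-SVZ call was lost (−4.01, adjusted p = 0.17), and it was also lost with no filter on low genes (adjusted p = 0.0652). Without JKO cortex 1 or JKO cortex 3 Pear1 was called in cortex (adjusted p = 0.0289 and 0.0378). Within title prefix 7814 the cortex difference in log2 CPM was −3.77, within 8156 it was −4.21 and over both −4.13. In V-SVZ the difference was −4.04 within 8156 and −4.11 over both, and 7814 held no JKO V-SVZ library. In the authors' deposited table Pear1 changed by −3.92 in cortex (adjusted p = 1.9e-58) and by −3.76 in V-SVZ (adjusted p = 8.5e-13). Lrrc71 and Insrr overlap the annotated span of Pear1 (87736923 to 87748625 and 87796951 to 87816101), so reads in the shared stretches are of uncertain origin.

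**Figure D1:**
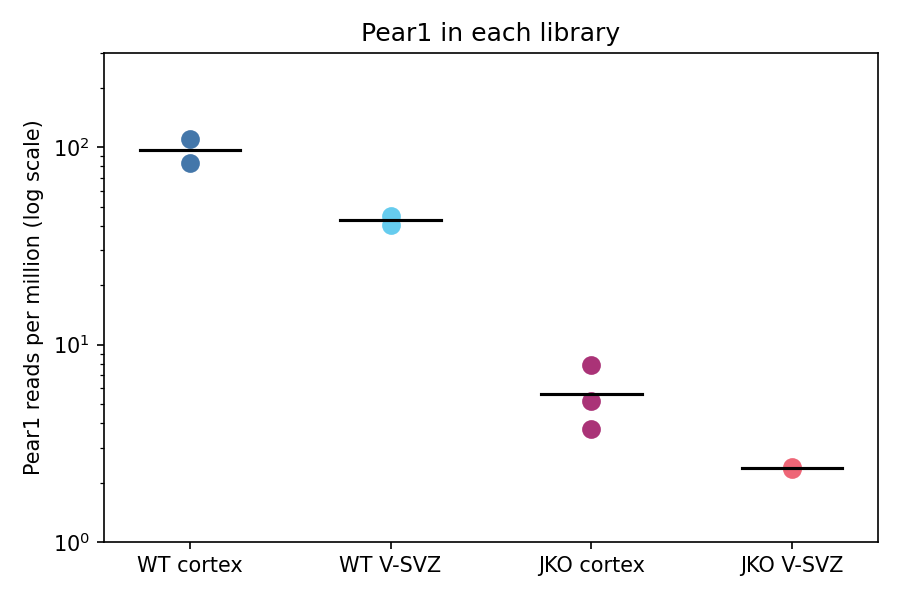
Pear1 CPM in each of the 9 libraries (dots, logarithmic axis) by group, with bars at the group means. The JKO libraries lie between 2.33 and 7.92 CPM and the WT libraries between 40.4 and 110 CPM.

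The first comparison asked how V-SVZ preparations differ from cortex preparations in WT mice. Ependymal genes, of the ciliated cells that line the ventricle, stood highest among the called lists apart from choroid plexus, with a median log2 fold change of 2.55 over 20 genes. Dnah12, a ciliary dynein, rose by 2.96 ± 0.27 and Ccdc153 by 2.63 ± 0.25 (log2 ± SE, n = 2 and 2, limma adjusted p = 0.0248 for both). Of the neuroblast list (24 genes, median 1.45), Igfbpl1 rose by 1.93 ± 0.25, the neuronal surface protein gene Cd24a by 1.64 ± 0.23 and Dlx1, a transcription factor of inhibitory neuron precursors, by 1.83 ± 0.35. Endothelial genes were lower (20 genes, median −1.48), among them Sox18 (−1.62 ± 0.13) and the VEGF receptor Flt1 (−1.53 ± 0.18). So were mural cell and fibroblast genes (19 genes, median −1.31), with Anpep at −1.58 ± 0.13 and Notch3 at −1.31 ± 0.12. Called members numbered 18 up for ependymal, 3 up for neuroblast, 17 down for endothelial and 14 down for mural genes over all genes tested, and 20, 20, 20 and 17 adjusted over the list alone. On the homeostatic scale, which shifted the median of all genes by 0.12, they numbered 20, 11, 10 and 7 over all genes tested. The choroid plexus list had a median of 3.49 over 17 genes with no member called either way (8 up on the homeostatic scale), and its level was 4.15 in WT cortex 1 and 0.13 in WT cortex 2 against 5.47 ± 0.0446 (SD, n = 2) in WT V-SVZ. Erythroid genes were lower (10 genes, median −1.18), with Alas2 of heme synthesis at −1.43 ± 0.17. Camera adjusted p-values were 8.3e-13 for ependymal, 1.7e-06 for neuroblast, 3.7e-12 for endothelial, 4.9e-12 for mural, 0.0011 for choroid plexus and 1.7e-06 for erythroid genes. For all 14 lists called in this comparison the adjusted p was 0.822 to 0.843 with an estimated correlation.

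Among microglial genes, those of the disease- and development-associated state were higher in WT V-SVZ (24 genes, median log2 0.71, camera adjusted p = 0.00013). Its called members over all genes were the growth factor Igf1 (1.62 ± 0.28, 48.4 ± 11.9 to 166 ± 61.5 CPM, SD, n = 2 and 2), the integrin Itgax (2.40 ± 0.44) and the protease Ctsl (1.06 ± 0.20), and 14 members rose and 1 fell adjusted over the list alone. Spp1, which encodes osteopontin, had a log2 fold change of 2.18 ± 0.56 and was not called (adjusted p = 0.0917). The lysosome list had a median of 0.24 over 37 genes (camera adjusted p = 0.0047), with Ctsl as its called member, and was lost without WT cortex 1 or WT V-SVZ 1. Homeostatic markers, of the resting microglial identity, had a median of −0.11 (0.02 after scaling on this list) and were not called, with values of −0.15 ± 0.32 for P2ry12 and −0.78 ± 0.50 for Tmem119. Border-associated macrophage genes, of the macrophages along vessels and meninges, were lower (17 genes, median −1.38, camera adjusted p = 9.5e-06). Cd163 (−1.83 ± 0.19), F13a1 (−1.73 ± 0.19) and Lyve1 (−2.22 ± 0.27) fell, while the mannose receptor gene Mrc1 stood at −0.66 ± 0.38 and was not called. Over all genes 5 members of that list fell, with Ccl8 (−4.49 ± 0.60) and Pf4 (−1.62 ± 0.29) as the others, and the folate receptor gene Folr2 rose (1.36 ± 0.27). Of these Folr2 and Pf4 were named after their values were seen, and adjusted over the list alone 12 fell and 1 rose, against 2 and 0 over all genes on the homeostatic scale. Of the engulfment list (median −0.12, 0.00 after homeostatic scaling, not called), the called members were Pear1 (−1.29 ± 0.17, adjusted p = 0.025), the scavenger receptor Scarf1 (−1.55 ± 0.21) and Mfge8 (−0.89 ± 0.12), a bridge to dying cells, and on the homeostatic scale 0 members of this list were called. Pear1 in WT V-SVZ was 44.2% of its level in WT cortex, with differences in log2 CPM of −1.29 within prefix 7814, −1.04 within 8156 and −1.16 over both.

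The largest called increases from WT cortex to WT V-SVZ were in Wnt8b (4.30 ± 0.74, a Wnt ligand), the homeobox gene Lhx9 (4.30 ± 0.84), Krt15 (3.39 ± 0.42), the neuropeptide gene Tac2 (3.33 ± 0.44), Sap30bpos (3.26 ± 0.44), Kif12 (3.20 ± 0.55), Rmst (3.13 ± 0.47), Npy2r (3.11 ± 0.50), Cdc20b (3.10 ± 0.49) and Lrp2 (3.07 ± 0.49). Lrp2, an endocytic receptor of ependymal cells, went from 3.07 ± 2.03 to 25.4 ± 5.90 CPM (SD, n = 2 and 2). Several of the others were low in both groups. Wnt8b went from 0.134 ± 0.0888 to 3.27 ± 2.48 CPM and Lhx9 from 0.0866 ± 0.0889 to 1.56 ± 0.250 CPM. Tac2 went from 0.129 ± 0.0140 to 1.54 ± 0.430 CPM and Kif12 from 0.160 ± 0.0926 to 1.60 ± 0.517 CPM. Sap30bpos is an antisense gene, and without a stated strand setting its reads cannot be separated from those of its partner. The largest called decreases were in the chemokine Ccl8 (−4.49 ± 0.60), Retnla (−4.32 ± 0.81), the organic anion transporter Slc22a6 (−3.10 ± 0.60), Mfap5 (−2.94 ± 0.52), Nwd2 (−2.75), Fgfr4 (−2.62), Nrgn (−2.47 ± 0.27), Cacna1i (−2.47 ± 0.37), Adra1b (−2.45 ± 0.21) and Sncb (−2.43 ± 0.28). Nrgn, a postsynaptic protein of cortical neurons, went from 21.9 ± 3.78 to 4.35 ± 1.13 CPM (SD, n = 2 and 2). Ccl8 went from 0.945 ± 0.396 to 0.0345 ± 0.00720 CPM, close to no reads, and Retnla from 10.7 ± 10.1 to 0.448 ± 0.197 CPM. The rule for naming these 20 genes required that the groups' libraries do not overlap, and 58.1% of all genes tested met that requirement where chance gives 33.3%.

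Of 18934 genes tested, limma called 1394, of which 685 rose and 709 fell, and 1370 of them were also called in the authors' deposited table, which calls 2486. Of the remaining called lists, cell cycle (median −0.26, camera adjusted p = 0.0001), interferon response (−0.28, 0.0022), neural stem cell and astrocyte (−0.46, 0.0057), unfolded protein response (−0.18, 0.037) and lymphocyte (−0.65, 0.047) genes stood below other genes (adjusted p = 0.822 to 0.843 with an estimated correlation). Of the cell cycle, interferon, unfolded protein and lymphocyte lists 0 members fell, over all genes or adjusted over the list alone. The interferon gene Cmpk2 rose over all genes (1.27 ± 0.24), a call that was lost on the homeostatic scale. Of the astrocyte list 11 genes fell adjusted over the list alone, among them the bicarbonate cotransporter Slc4a4 (−1.06 ± 0.15) and connexin gene Gja1 (−0.78 ± 0.13), and Id4 rose (1.44 ± 0.19), against 5 and 1 over all genes and 0 and 1 over all genes on the homeostatic scale. Differences in log2 CPM within prefixes 7814 and 8156 were 1.91 and 3.30 for ependymal (2.60 over both), 0.79 and 1.96 for neuroblast (1.38), −1.27 and −1.25 for endothelial (−1.26), and 0.97 and 0.76 for disease- and development-associated genes (0.87). They parted for homeostatic genes at 0.38 and −0.37 (0.01 over both) and for the inflammatory list at 0.80 and −0.35 (0.22). The count of called genes depended on the libraries: it was 0 without WT V-SVZ 2 and 596 without WT cortex 2, and the split became 754 higher and 179 lower without WT cortex 1. Of the 20 named largest changes, 0 stayed called without WT V-SVZ 2, 11 without WT cortex 2 and 8 without WT V-SVZ 1. Interferon response was lost without WT V-SVZ 2, astrocyte without WT V-SVZ 1, and unfolded protein response and lymphocyte without WT cortex 2 or WT V-SVZ 2.

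**Figure D2:**
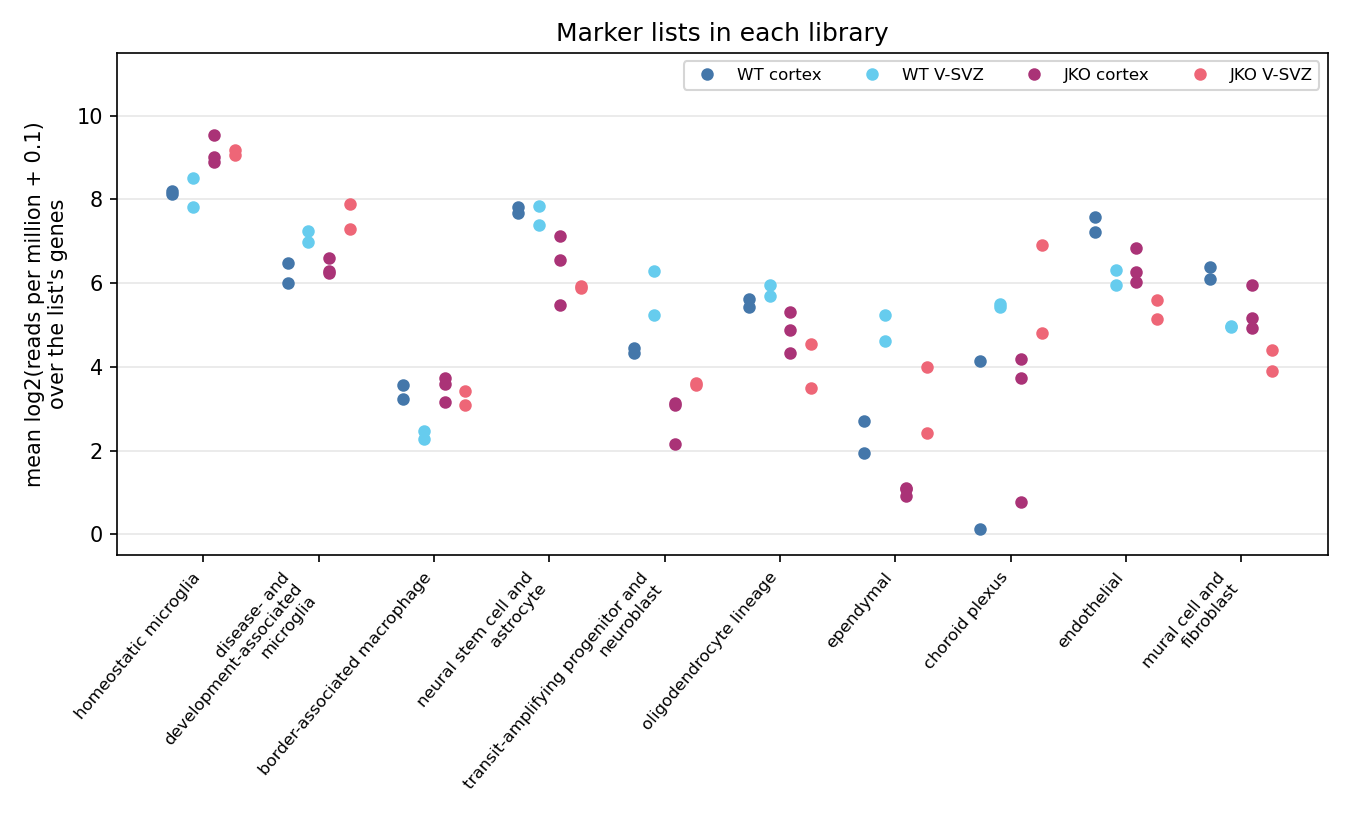
Mean log2(CPM + 0.1) over the genes of 10 marker lists, 1 dot per library, coloured by group. Homeostatic microglia lie at 8.16 ± 0.0587 in WT cortex (SD, n = 2) and 9.15 ± 0.352 in JKO cortex (SD, n = 3), and choroid plexus genes spread from 0.13 to 4.15 between the WT cortex libraries.

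The same regional comparison was made in JKO mice, with 3 cortex and 2 V-SVZ libraries. Genes of the disease- and development-associated state stood above other genes in JKO V-SVZ (median log2 1.15, camera adjusted p = 7.7e-12), and so did lysosome genes (0.45, 7.7e-10). Of their members 13 and 7 rose adjusted over the list alone, among them the glycoprotein gene Gpnmb (2.94 ± 0.36), Itgax (2.97 ± 0.35), the lysosomal membrane gene Cd63 (1.18 ± 0.14), the proton pump subunit Atp6v0d2 (2.94 ± 0.33) and Ctsl (1.37 ± 0.21). Igf1 went from 44.0 ± 8.45 to 232 ± 42.9 CPM (SD, n = 3 and 2, log2 2.43 ± 0.23) and Spp1 from 216 ± 135 to 1840 ± 883 CPM (3.20 ± 0.55), and neither was called over all genes (adjusted p = 0.0964 and 0.106). Ependymal (2.30, 3.0e-15), choroid plexus (3.28, 6.8e-07) and neuroblast genes (0.91, 5.6e-05) were also higher, with 19, 0 and 9 members up adjusted over the list alone and 1 neuroblast gene down. Examples were the cilia regulator Foxj1 (2.48 ± 0.37) and Dlx1 (1.73 ± 0.35). The choroid plexus level was 0.76, 4.19 and 3.73 in JKO cortex 1, 2 and 3, and 4.80 and 6.91 in JKO V-SVZ 2 and 3. Glycolysis genes had a median of 0.49 (9.4e-05), with Pgk1 at 1.01 ± 0.17 and 7 members up adjusted over the list alone. Endothelial (−1.08, 1.6e-10), mural (−1.18, 1.2e-08), cell cycle (−0.42, 1.6e-10), oligodendrocyte (−0.84, 0.0011), erythroid (−0.93, 0.0025) and interferon genes (−0.21, 0.026) were lower, with 16, 12, 8, 1, 0 and 0 members down adjusted over the list alone. Ly6c1 (−1.22 ± 0.22) and the junction gene Cdh5 (−1.17 ± 0.23) of the endothelial list, Kif23 (−0.65 ± 0.13) of the cell cycle list and the myelin gene Cldn11 (−1.91 ± 0.38) were examples. The dissociation and immediate early list was called as well (0.22, 0.0076) with 0 members past the test. On the homeostatic scale 11 disease- and development-associated, 5 lysosome and 17 ependymal genes were called higher over all genes. For the 13 called lists the adjusted p was 0.673 to 0.800 with an estimated correlation.

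No gene was called by limma in JKO V-SVZ against JKO cortex among 17165 tested, with 2833 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0964. In edgeR 0 genes were called with 2973 at an unadjusted p under 0.05, DESeq2 called 1605, and the authors' deposited table calls 943. The genes with the smallest p, none called, were the heparanase gene Hpse (2.94 ± 0.25), Igf1, the chemokine Ccl9 (1.96 ± 0.19), the mitophagy gene Bnip3 (1.57 ± 0.16) and Cd28 (3.05 ± 0.31) with higher values in V-SVZ. Those with lower values were the transporter Slc47a1 (−5.61 ± 0.53), the homeobox gene Six2 (−5.30 ± 0.58), Crabp2 (−4.48 ± 0.50), Ccn3 (−4.85 ± 0.55) and the connexin gene Gjb6 (−3.08 ± 0.37), several of which are expressed in meningeal cells. Hpse went from 9.50 ± 1.80 to 71.5 ± 15.4 CPM and Slc47a1 from 12.9 ± 6.05 to 0.231 ± 0.115 CPM (SD, n = 3 and 2). P2ry12 (−0.00 ± 0.33), Tmem119 (−0.54 ± 0.27), Mrc1 (−0.42 ± 0.18), Il1b (−0.17 ± 0.28) and Apoe (1.71 ± 0.34) were not called. Pear1 stood at −1.14 ± 0.36 (adjusted p = 0.199), with a log2 CPM difference of −0.87 within prefix 8156 and −1.15 over both. Within prefix 8156 the difference was 1.17 for disease- and development-associated genes (1.21 over both), 0.45 for lysosome (0.52), 2.12 for ependymal (2.17) and −0.90 for mural genes (−1.21), and prefix 7814 held no JKO V-SVZ library. Without JKO cortex 2 limma called 22 genes. Interferon response was lost without JKO cortex 3 or JKO V-SVZ 3, and the immediate early, oligodendrocyte and erythroid lists without JKO V-SVZ 2.

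In cortex, loss of Jedi-1 was compared between 3 JKO and 2 WT libraries. Homeostatic microglial genes stood above other genes in JKO (22 genes, median log2 1.13, camera adjusted p = 6.4e-10), as did inflammatory cytokines and chemokines (29 genes, 1.20, 6.4e-10). Of the homeostatic list 21 genes rose adjusted over the list alone, such as the endocytic adaptor Bin1 (1.15 ± 0.18), Crybb1 (1.24 ± 0.20) and Mertk (1.10 ± 0.20), a receptor for dying cells. On the homeostatic scale, which holds this list level by construction, 0 were higher and 1 lower over all genes. Of the inflammatory list 23 rose and 1 fell adjusted over the list alone (0 and 2 over all genes on the homeostatic scale), with the cytokine Il1a at 1.69 ± 0.21, the adhesion molecule Icam1 at 0.95 ± 0.10 and the NF-kB inhibitor Tnfaip3 at 1.54 ± 0.22. P2ry12 went from 406 ± 8.90 to 995 ± 406 CPM (1.34 ± 0.32) and Il1b from 16.3 ± 4.64 to 36.5 ± 6.32 CPM (1.30 ± 0.24, SD, n = 2 and 3). Lists of most other cell types stood below other genes: neuroblast (median −1.64, 3.2e-09), cortical neuron (−1.33, 1.5e-07), ependymal (−1.30, 1.5e-07), neural stem cell and astrocyte (−1.40, 9.6e-06), endothelial (−0.91, 3.9e-07), mural (−0.59, 0.0006) and erythroid (−0.98, 0.0026), while the oligodendrocyte list was not called (−0.64, 0.102). Of their members 22, 15, 14, 1, 19, 6 and 0 fell adjusted over the list alone. Examples were Dlx1 (−1.99 ± 0.33), the neuronal tubulin Tubb3 (−1.84 ± 0.33), the neuronal splicing factor Rbfox3 (−1.66 ± 0.26) and Tmem212 (−2.23 ± 0.36). On the homeostatic scale 24, 19, 20, 19, 20, 19 and 9 were lower over all genes, as were 12374 of all 17800 genes tested. For the 15 called lists the adjusted p was 0.706 with an estimated correlation.

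Several functional lists, the dissociation and immediate early list and the neutrophil list also stood higher in JKO cortex as the authors scaled the libraries. Their medians were below 0 once libraries were scaled on the homeostatic list, which shifted the median of all genes by −1.11. The camera p-values below belong to the authors' scaling. Lysosome genes had a median of 0.53 (−0.57 on the homeostatic scale, camera adjusted p = 1.4e-08), antigen presentation 0.71 (−0.40, 1e-06), immediate early 0.95 (−0.15, 2.1e-06), cell cycle 0.28 (−0.83, 7e-05), engulfment 0.42 (−0.69, 0.004) and neutrophil genes 0.70 (−0.41, 0.013), with an adjusted p of 0.706 for each with an estimated correlation. The inflammatory median became 0.09, and the homeostatic one became 0.03, which this scaling fixes in advance. Adjusted over the list alone, 20 of 37 lysosome genes rose, as did 17 of 22 antigen presentation genes with 1 lower, 6 of 30 immediate early, 0 cell cycle, 19 of 38 engulfment genes with 6 lower, and 1 neutrophil gene, Csf3r (1.36 ± 0.22). On the homeostatic scale 12374 of all 17800 genes tested were called lower and 4 higher, so lower calls were common to most genes. The counts there were 0 lysosome genes higher and 14 lower, 0 and 4 for antigen presentation, and 1 and 6 for immediate early. They were 0 and 36 for cell cycle, 0 and 16 for engulfment and 0 and 1 for neutrophil genes. Examples were the sialidase Neu1 (0.76 ± 0.15), the costimulator Cd86 (1.28 ± 0.16), H2-DMa (0.93 ± 0.14), the stress factor Atf3 (1.29 ± 0.27), and Dock2 (1.11 ± 0.16) and Elmo1 (1.05 ± 0.18), which act together in engulfment. The disease- and development-associated list was not called (0.21, −0.90 on the homeostatic scale), with Igf1 at −0.01 and Spp1 at −0.23. Within prefixes 7814 and 8156 the log2 CPM difference was 0.77 and 1.07 for homeostatic (0.98 over both), 1.14 and 0.57 for inflammatory (0.84), 0.37 and 0.38 for lysosome (0.41), −1.34 and −1.69 for neuroblast (−1.59) and −1.08 and −1.51 for cortical neuron genes (−1.33). The choroid plexus list, not called, went from −3.38 to 3.83 between those prefixes (0.75 over both). The immediate early level was 6.88 in WT cortex 1 and 8.03 in JKO cortex 1, of prefix 7814. In prefix 8156 it was 7.57 in WT cortex 2, and 7.99 and 7.89 in JKO cortex 2 and 3. Whether a response to dissociation also raised the inflammatory list was not tested.

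Of 17800 genes tested in cortex, limma called 0 (lowest adjusted p = 0.0751), with 6049 at an unadjusted p under 0.05. In edgeR 0 were called with 5983 at an unadjusted p under 0.05, DESeq2 called 4438, and the authors' deposited table calls 3784. The genes with the smallest p, none called, were the oxysterol receptor Gpr183 (1.40 ± 0.12, 39.9 ± 5.24 to 96.1 ± 4.05 CPM), Nfkbie (1.21 ± 0.11), Rgs1 (1.95 ± 0.18), Lncpint (1.56 ± 0.15) and Rab20 (1.30 ± 0.13), which became 0.29, 0.10, 0.84, 0.45 and 0.19 on the homeostatic scale. With lower values they were Cd24a (−1.24 ± 0.13), the tubulin regulator Stmn2 (−1.24 ± 0.15), Caln1 (−1.77 ± 0.22), Fam167a (−1.60 ± 0.21) and Pear1. Without JKO cortex 1 limma called 3163 genes, and without JKO cortex 3 it called 1242.

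The V-SVZ genotype comparison asked the same of 2 JKO and 2 WT V-SVZ libraries. Among the 10 largest called decreases in JKO were Neurog2 (−3.36 ± 0.53, log2 ± SE), Eomes (−3.09 ± 0.53), Neurod1 (−2.86 ± 0.46) and Scrt2 (−2.64 ± 0.46), transcription factors of neuronal precursors. Eomes went from 12.2 ± 2.26 to 1.27 ± 0.746 CPM and Neurod1 from 5.05 ± 0.327 to 0.579 ± 0.207 CPM (SD, n = 2 and 2). The neuroblast list (median −2.05, camera adjusted p = 2e-10) had 12 members down over all genes and 23 of 24 adjusted over the list alone, including the growth factor receptor Egfr (−2.38 ± 0.25), Sox11 (−2.17 ± 0.32) and Igfbpl1 (−1.78 ± 0.26). Neural stem cell and astrocyte genes (−1.62, 2.7e-10) had 18 and 20 down, with Fabp7 at −2.17 ± 0.24, Gja1 at −1.61 ± 0.19 and Ptprz1 at −2.42 ± 0.29. Oligodendrocyte genes (−1.58, 1.2e-06) had 9 and 13 down, with Gpr17 at −2.42 ± 0.30, Sox10 at −2.23 ± 0.29 and Bcas1 at −2.04 ± 0.24. Ependymal (−1.46, 1.1e-05) and cortical neuron genes (−1.60, 0.0003) had 0 and 3 down over all genes, the latter Neurod1, Mapt and Tbr1, and 15 and 12 adjusted over the list alone. Of the vascular lists, endothelial genes were at −0.51 (0.0021, 0 members down either way) and mural genes were at −0.47 (0.0022), of which Abcc9, Vtn and Kcnj8 fell over all genes and 6 adjusted over the list alone. Erythroid genes had a median of −0.64 (0.0068). Scaled on the homeostatic list, 24 neuroblast, 23 astrocyte, 18 oligodendrocyte, 20 ependymal and 15 cortical neuron genes were lower over all genes. So were 19 endothelial, 14 mural and 8 erythroid genes, and 6742 of all 17981 genes tested. The other named decreases were in Mroh3 (−3.28), Cavin4 (−3.11), Htr5b (−2.98), Tecta (−2.88) and Ptx3 (−2.74). For the 21 called lists the adjusted p was 0.639 to 0.771 with an estimated correlation.

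Microglial and macrophage lists and the dissociation and immediate early list stood above other genes in JKO V-SVZ. Scaling on the homeostatic list, which shifted the median of all genes by −1.23, turned most of their medians below 0. The camera p-values below belong to the authors' scaling. Homeostatic genes had a median of 1.21 (−0.01 on the homeostatic scale, camera adjusted p = 2e-10), lysosome 0.84 (−0.39, 1.7e-11), border-associated macrophage 1.27 (0.04, 1.8e-07), immediate early 0.93 (−0.30, 9.1e-09), inflammatory 0.96 (−0.27, 2.5e-06) and antigen presentation genes 0.90 (−0.33, 6.8e-06). With an estimated correlation the adjusted p was 0.639 to 0.771 for these and the other called lists. Adjusted over the list alone, 21, 20, 14, 22, 12 and 9 of their members rose, with 1 inflammatory and 1 antigen presentation gene lower. On the homeostatic scale 0 members of these 6 lists were higher over all genes, which for the homeostatic list was fixed in advance. There 2 immediate early, 1 inflammatory and 1 antigen presentation gene were lower, against 6742 of all 17981 genes tested. Over all genes the immediate early factor Egr2 rose (1.35 ± 0.22, 86.1 ± 1.79 to 181 ± 15.3 CPM, SD, n = 2 and 2). P2ry12 (1.48 ± 0.36, adjusted p = 0.0662), Tmem119 (1.68 ± 0.47), Siglech (1.39 ± 0.31), the protease Ctss (1.15 ± 0.30) and the chemokine Ccl2 (1.42 ± 0.34) were not called over all genes. The disease- and development-associated (0.79, −0.44 on the homeostatic scale, 1.3e-05), glycolysis (0.40, −0.83, 0.0079) and interferon lists (0.32, −0.91, 0.01) were called too. So were the choroid plexus (0.68, −0.55, 0.016), unfolded protein (0.39, −0.84, 0.017) and neutrophil lists (1.09, −0.14, 0.0026). On the homeostatic scale 0 of their members were higher, and 2, 5, 4, 0, 6 and 0 were lower over all genes. The unfolded protein list had a mean log2 CPM of 5.70 in WT and 5.65 in JKO V-SVZ. The engulfment list was called (0.82, −0.41 on the homeostatic scale, 0.00025) with members both ways: Megf10 (−2.03 ± 0.27), a receptor related to Jedi-1, and Mfge8 (−0.98 ± 0.17) fell, Pear1 fell as given above, and Itgb3 was higher at 1.11 ± 0.21 but −0.12 on the homeostatic scale. The receptor gene Havcr2, named after its value was seen, was the other called increase (1.07 ± 0.20, −0.16 on the homeostatic scale). Adjusted over the list alone 18 engulfment genes rose and 6 fell, against 0 and 9 over all genes on the homeostatic scale. With quantile normalization the engulfment, unfolded protein, glycolysis and choroid plexus lists lost their calls.

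Of 17981 genes tested in V-SVZ, limma called 685, of which 26 rose and 659 fell, and 647 were also called in the authors' deposited table, which calls 1897 (548 higher, 1349 lower). DESeq2 called 3232, of which 983 were higher and 2249 lower. Among the 10 largest increases were Neurl3 (1.48 ± 0.29), Egr2, Il21r (1.32 ± 0.25), Mir142hg (1.28 ± 0.17), the inhibitory Fc receptor Fcgr2b (1.27 ± 0.21, 43.9 ± 5.76 to 87.3 ± 0.326 CPM, SD, n = 2 and 2), Rgs2 (1.26 ± 0.24), Mylip (1.24 ± 0.24), Hpgd (1.23 ± 0.23) and Evi2a (1.21 ± 0.21). On the homeostatic scale these were 0.25, 0.12, 0.09, 0.05, 0.04, 0.03, 0.01, 0.01 and −0.02 in the same order. Of the 20 largest called changes 5 stayed called with quantile normalization, 10 on the homeostatic scale and 1 with all 9 libraries in 1 fit. Within prefix 8156 the log2 CPM difference was 1.29 for homeostatic (0.95 over both), 0.57 for lysosome (0.53), 0.98 for border-associated macrophage (0.89), −2.69 for neuroblast (−2.16), −1.94 for astrocyte (−1.71) and −0.60 for endothelial genes (−0.77), and prefix 7814 held no JKO V-SVZ library. Without WT V-SVZ 2 limma called 0 genes, and with no filter on low genes also 0, while without JKO V-SVZ 3 it called 3776 (1216 higher, 2560 lower). The split also moved without WT V-SVZ 1 (171 higher, 590 lower) and without JKO V-SVZ 2 (86 higher, 717 lower). Of the 20 largest changes 0 stayed called without WT V-SVZ 2, 13 without WT V-SVZ 1, 12 without JKO V-SVZ 2 and 20 without JKO V-SVZ 3. List calls were lost for endothelial without WT V-SVZ 1, for interferon, unfolded protein and neutrophil without WT V-SVZ 2 or JKO V-SVZ 2, for erythroid without WT V-SVZ 2, for glycolysis without JKO V-SVZ 2, and for choroid plexus without JKO V-SVZ 3, where its median turned to −0.15.

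**Figure D3:**
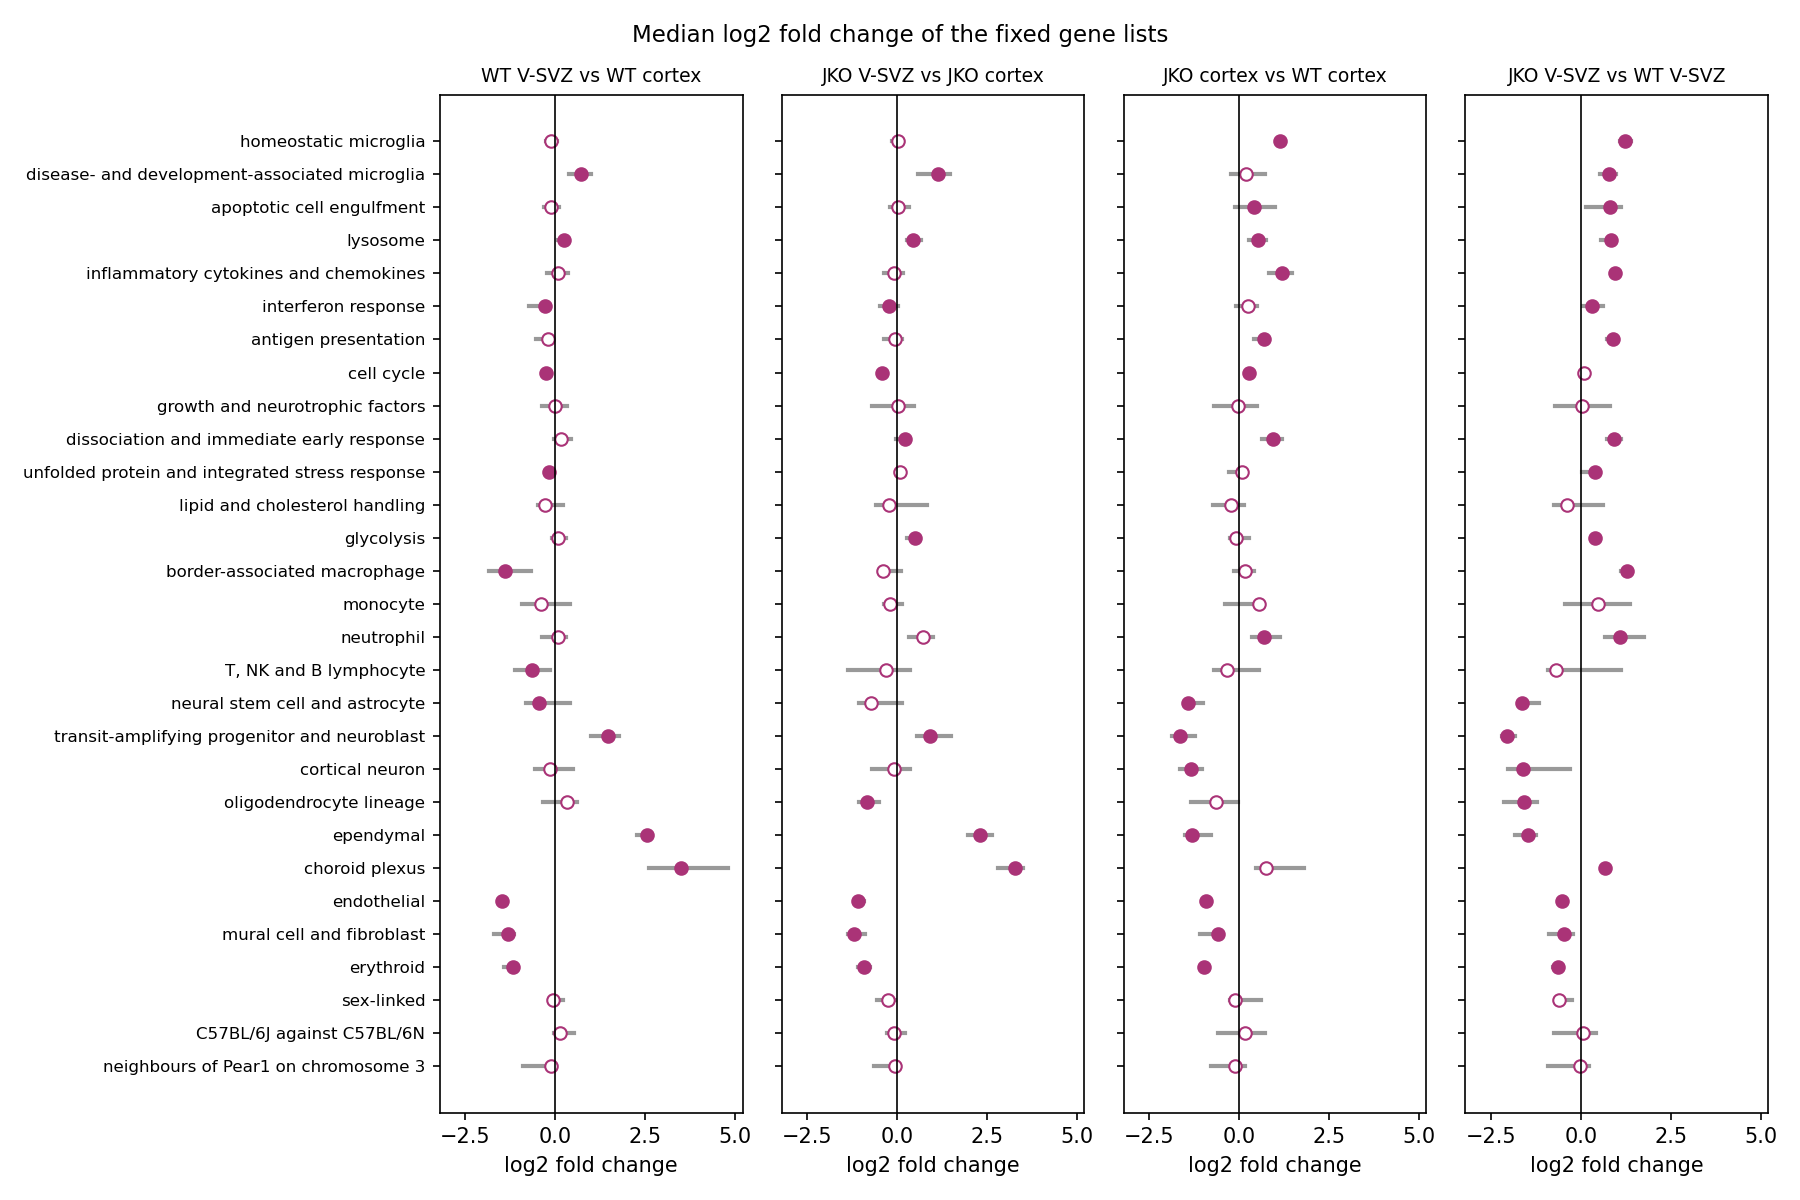
Median log2 fold change of each of the 29 lists in the 4 comparisons (circles, filled where the camera adjusted p was under 0.05), with grey bars from the lower to the upper quartile of its genes. In JKO against WT V-SVZ the lysosome list sits at 0.84 with the authors' scaling (−0.39 on the homeostatic scale) and the neuroblast list at −2.05.

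Whether the regional difference itself changed with genotype was tested by the interaction. Igf1 differed between regions by 1.62 ± 0.28 in WT and by 2.43 ± 0.23 in JKO (log2 ± SE), and Pear1 by −1.29 ± 0.17 and −1.14 ± 0.36, and no gene was called by limma for a difference between the genotypes. Among 18221 genes 737 had an unadjusted p under 0.05 where chance gives 911, edgeR called 0 with 819 at an unadjusted p under 0.05, and DESeq2 called 8. Across genes, region effects in WT and JKO had a Pearson r of 0.775 and a Spearman rho of 0.581 over 17131 genes, with 67.5% of the same sign. Genotype effects in cortex and V-SVZ had an r of 0.768 and a rho of 0.771 over 17378 genes, with 78.6% of the same sign. Genes are not independent replicates, so no p is given for these. The compared effects share no library, and the labels do not say whether they share animals. Of 1363 genes called between WT regions and tested in JKO, 1354 had the same direction there, with a median size of 1.45 in WT and 1.17 in JKO. All 681 genes called between genotypes in V-SVZ and tested in cortex had the same direction in cortex, with median sizes of 1.74 and 1.21.

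**Figure D4:**
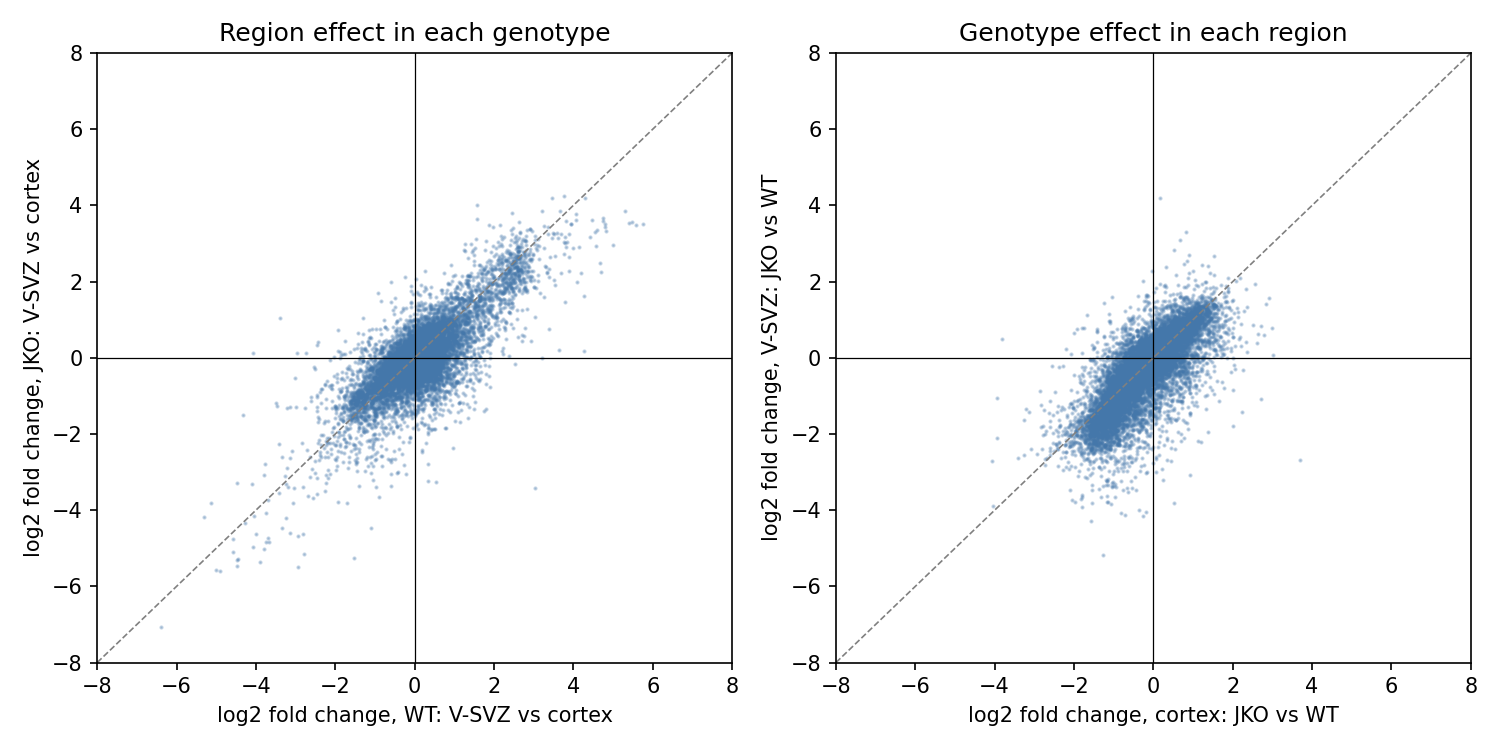
Log2 fold change of each gene, for the region effect in WT against that in JKO and for the genotype effect in cortex against that in V-SVZ, 1 point per gene, with a dashed line of equality. The Pearson r is 0.775 for region and 0.768 for genotype effects.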

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

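The list tests of the interaction and the tests of explanations in this part were chosen after the results were seen, while the test of single genes for the interaction was planned. In 10 lists the difference between V-SVZ and cortex was larger or smaller in JKO than in WT by camera of limma, while limma called 0 genes (737 at an unadjusted p under 0.05), edgeR 0 and DESeq2 8. Border-associated macrophage genes had a median interaction of 1.18 on the log2 scale (adjusted p = 1.89e-07; 0.77 to 1.42 when each library was left out). This call was kept without each of the 9 libraries but not with an estimated correlation (adjusted p = 0.907). For disease- and development-associated genes the median was 0.498 (adjusted p = 0.000123; 0.17 to 0.82), lost without WT cortex 2 or JKO V-SVZ 2. Lysosome (0.238, adjusted p = 4.6e-05), unfolded protein (0.297, 0.000709), glycolysis (0.444, 5.75e-05) and oligodendrocyte genes (−0.817, 0.000357) were lost without JKO V-SVZ 2. Endothelial genes (0.400, adjusted p = 0.00131) were lost without WT cortex 1, WT V-SVZ 2 or JKO V-SVZ 3, and cell cycle genes (−0.179, 0.00156; −0.32 to 0.01 over the libraries left out) without WT cortex 1, WT V-SVZ 1 or JKO V-SVZ 3. Engulfment genes (0.174, adjusted p = 0.012; −0.01 to 0.36) were lost without WT cortex 2, WT V-SVZ 2, JKO cortex 1 or JKO V-SVZ 2, and neuroblast genes (−0.363, 0.0128; −0.86 to 0.12) without WT V-SVZ 2, JKO cortex 1, JKO cortex 2 or JKO V-SVZ 3. With an estimated correlation the adjusted p was 0.907 for all 10 lists.

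Most neuron and glia lists were lower and microglial lists higher in JKO than in WT libraries as the authors scaled them, with the lysosome list turning to −0.57 in cortex and −0.39 in V-SVZ on the homeostatic scale. In V-SVZ the values argue against a smaller carry-over of every other cell type alike. Neural minus vascular lists differed there by −0.985 in log2 CPM (WT −0.43 and 0.21, JKO −1.09 in both libraries). This rests on 2 libraries per group and on a rule set after the data were seen. In cortex such a carry-over cannot be told apart from a selective loss (−0.304, with JKO cortex 2 at −2.09 above both WT libraries). For the higher homeostatic list in cortex the values argue against a batch marked by the title prefix. The list stood above WT by 0.765 within 7814 and 1.07 within 8156, each from 1 WT library, while WT cortex libraries of different prefix differed by 0.083. In V-SVZ such a batch cannot be excluded, as only prefix 8156 holds both genotypes. The difference there, 1.29, rests on 1 WT library, and the WT V-SVZ libraries differed by 0.67. The inflammatory minus the homeostatic list was lower in JKO V-SVZ by −0.424 (WT −4.005 and −3.99, JKO −4.18 and −4.67). This cannot exclude more inflammatory transcript per microglial cell, because the libraries hold other cells whose share also changed. In cortex more inflammatory transcript per cell cannot be told apart from a higher share of microglia because the libraries overlap (−0.14). The dissociation and immediate early list was higher in each JKO library than in each WT library of its region. Its level in V-SVZ was 7.73 and 7.34 in WT and 8.24 and 8.03 in JKO. A response to dissociation therefore cannot be excluded for the inflammatory list in either region. Carry-over that differs by cell type, which CD11b selection should limit, may account for the lower neural lists as well as a loss of neural cells near microglia. Neither was tested, and other sources are not excluded.

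Pear1 was lower in WT V-SVZ than in WT cortex. Relative to the endothelial list it differed by 0.0969 in log2 CPM, with overlapping libraries (WT cortex −0.80 and −0.83, WT V-SVZ −0.82 and −0.63), which is consistent with fewer endothelial cells among the V-SVZ cells as a candidate source. The endothelial gene Cldn5 stood at 948 and 744 CPM in WT cortex and 343 and 260 CPM in WT V-SVZ, although CD11b selection should remove such cells. Less Pear1 per microglial cell cannot be told apart from this, as Pear1 minus the homeostatic list also differed (−1.17) and the libraries hold both cell types.

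Disease- and development-associated and lysosome genes were higher in V-SVZ than in cortex in both genotypes. The values argue against a higher share of microglia as the only cause, which would raise both lists alike. The lower quartile of the disease- and development-associated list lay above the upper quartile of the homeostatic list by 0.347 in WT and 0.425 in JKO (log2). These quartiles are over genes, not libraries, and the test did not cover the lysosome list. A higher share with less homeostatic transcript per cell would pass the same test and stays open. RNA of choroid plexus or ependymal cells cannot be excluded: the disease- and development-associated level followed these lists between the WT V-SVZ libraries (0.267) but went against them between the JKO ones (−0.601) and in WT cortex, where the library with Ttr at 2982 CPM had the lower level (6.01) and that with 7.07 CPM the higher (6.48), each from single libraries. A different microglial state was consistent with the smallest gap between V-SVZ and cortex libraries of a genotype in disease- and development-associated minus homeostatic genes, 0.198 in WT and 0.521 in JKO. While contamination stays open the pattern may have either source.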

How the results depend on the processing

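The homeostatic scaling, the fit of all 9 libraries and the fit of prefix 8156 alone were chosen after seeing the data; the other alternatives were planned. Counts of called genes depended on the tool, the scaling, the filter, the fit and single libraries, and for the changes below the cause was not tested. In WT V-SVZ against WT cortex (1394 genes), DESeq2 called 2950, the homeostatic scaling 816 (659 higher, 157 lower, against 685 and 709) and the fit of all 9 libraries 422; leaving out each library gave 0 to 1220. In JKO V-SVZ against JKO cortex (0 genes in limma), quantile normalization called 23, DESeq2 1605, the homeostatic scaling 627, all 9 libraries 431, and leaving out each library 0 to 22. In JKO against WT cortex (0 genes in limma), quantile normalization called 555, DESeq2 4438, the homeostatic scaling 12378 (4 higher, 12374 lower), prefix 8156 alone 13, all 9 libraries 1, and leaving out each library 0 to 3163. In JKO against WT V-SVZ (685 genes, 26 higher and 659 lower), no filter called 0, quantile normalization 327, DESeq2 3232, the homeostatic scaling 6743 (1 higher, 6742 lower), all 9 libraries 1, and leaving out each library 0 to 3776. The homeostatic scaling shifted the median of all genes by 0.12 in WT V-SVZ against WT cortex and by −1.11 and −1.23 between genotypes in cortex and V-SVZ, which is why most calls there became lower. DESeq2 called 8 genes for the interaction and limma 0. With an estimated correlation 0 lists were called in each of the 4 comparisons, against 14, 13, 15 and 21, while under every other alternative that was run 12 to 17, 13 to 15, 15 to 19 and 17 to 22 were called.

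Pear1 in cortex (−4.03, adjusted p = 0.0751) became called with quantile normalization (−3.95, 0.0264), DESeq2 (−3.97, 4.21e-31), the homeostatic scaling (−5.14, 0.00999), prefix 8156 alone (−4.12, 0.0339) and all 9 libraries (−4.10, 0.011), with −4.28 to −3.78 when each library was left out. In V-SVZ (−3.88, 0.0388) it lost its call with no filter (−3.88, 0.0652) and ranged from −4.05 to −3.72 when each library was left out, with the call lost without WT V-SVZ 2 (−4.01, 0.17). The correlation across genes of region effects (0.775) was 0.575 with no filter, 0.833 with a mean of at least 50, 0.717 with all 9 libraries and 0.627 to 0.772 when each library was left out. For genotype effects (0.768) it was 0.575 with no filter, 0.844 with a mean of at least 50, 0.734 in edgeR, 0.725 in DESeq2, 0.719 with all 9 libraries and 0.680 to 0.777 when each library was left out. Of the values for named genes, 2459 stayed on their side of the threshold in the same direction, 342 became called and 456 lost their call. Another 46 changed direction with a call in neither fit, or had no adjusted p, and 3 reversed with a call in either fit. Those 3 were Evi2a (−0.0202), Itgb3 (−0.12) and Havcr2 (−0.16) in JKO against WT V-SVZ under the homeostatic scaling. Leaving aside the estimated correlation, under which all 63 list calls were lost, of the values for called lists 667 kept direction and call, 33 lost the call and 1 reversed, choroid plexus in JKO against WT V-SVZ, at −0.15 without JKO V-SVZ 3 and 1.58 without JKO V-SVZ 2. With the title prefix as a covariate 1257 genes and 14 lists were called between WT regions, and 0 genes and 16 lists between cortex genotypes. It was not run for the other comparisons, and the alternative with the libraries described as outliers could not be run because the tables hold no column for them. Leaving out a library leaves some groups with 1 sample, which is then assumed to vary like the other group. No paired analysis was possible because the labels give no replicate numbers and tie no samples to an animal, and the numbers used here follow the order of the samples. The nearest to it is the fit with the prefix between WT regions, where each prefix holds 1 library of each group. The 3 deep libraries all had title prefix 7814, so depth and prefix cannot be told apart.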

Other observations

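The scaling values in this part come from the homeostatic scaling, which was chosen after seeing the data; the list tests were planned. Among growth and neurotrophic factors, Igf1 rose between WT cortex and WT V-SVZ while the EGF-family ligand Hbegf (−1.09 ± 0.14, log2 ± SE, n = 2 and 2, limma adjusted p = 0.0249) and the placental growth factor gene Pgf (−1.94 ± 0.29) fell. In JKO V-SVZ against WT V-SVZ the ligands Nrg1 (−2.13 ± 0.37) and Hgf (−1.62 ± 0.30) fell, and Vegfa stood at −0.92 ± 0.21 without a call (adjusted p = 0.0646). Adjusted over the list alone, 1 growth factor gene rose and 2 fell between WT regions and 2 rose and 4 fell in V-SVZ by genotype. On the homeostatic scale 2 were higher and 0 lower over all genes between WT regions, so Hbegf and Pgf lost their calls. By genotype in V-SVZ 0 were higher and 10 lower on that scale. The growth factor list was called in no comparison by camera. Its median between WT regions was 0.01 with a mean of 0.04 while the test pointed down, and by genotype in V-SVZ its median was 0.03 (−1.20 on the homeostatic scale) with a mean of −0.02. Without WT V-SVZ 2 limma called 0 genes between WT regions and in V-SVZ by genotype, a fit that leaves 1 library in the WT V-SVZ group. Of the inflammatory list, the chemokine Ccl9 rose (1.60 ± 0.20) and the nitric oxide synthase Nos2 fell (−1.57 ± 0.17) between WT regions, and Ccl9 stood at 1.96 ± 0.19 and Nos2 at −1.55 ± 0.34 between JKO regions, neither called. Of the antigen presentation list, Cd86 rose (0.81 ± 0.15) and Cd40 fell (−1.36 ± 0.17) between WT regions. On the homeostatic scale 0 antigen presentation genes were called there, and 1 inflammatory gene was higher and 0 lower. The calls of Cd86, Cd40 and Nos2 were thus lost on that scale, which shifted the median of all genes by 0.12. The homeostatic level was 8.50 and 7.83 in the WT V-SVZ libraries, and the scaling carries this spread into every gene. Calls lost between WT regions are therefore no sign that a change came from the share of microglia. Cortical neuron genes went both ways between WT regions. Neurod1 (2.78 ± 0.26), Nrn1 (1.35 ± 0.24) and Fezf2 (1.53 ± 0.29, named after its value was seen) rose. The glutamate transporter Slc17a7 (−1.51 ± 0.24) and Nrgn fell, with a list median of −0.15. On the homeostatic scale 1 cortical neuron gene was higher and 1 lower.

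Members of the lipid and cholesterol list went both ways. Between WT regions the desaturase Scd1 (−1.02 ± 0.13) and the sterol reductase Dhcr7 (−0.80 ± 0.11) fell, and the apolipoprotein Apoc1 rose (2.09 ± 0.22). In JKO against WT V-SVZ the sterol cyclase Lss (−1.09 ± 0.19) fell, Sqle stood at −1.02 ± 0.21 without a call, and Mylip rose (1.24 ± 0.24, 0.01 on the homeostatic scale). Between JKO regions the exporter Abcg1 (1.09 ± 0.18), Soat1 (0.83 ± 0.14) and Apoc1 (2.57 ± 0.33) had higher values, none called over all genes. Of the lipid and cholesterol list 3 rose and 6 fell between WT regions, 7 rose and 4 fell between JKO regions, 0 changed in cortex and 3 rose and 8 fell in V-SVZ by genotype, adjusted over the list alone. On the homeostatic scale 1 member was higher and 0 lower over all genes between WT regions, so Scd1 and Dhcr7 lost their calls. Between JKO regions 5 were higher and 0 lower. By genotype 0 were higher and 26 lower in cortex and 0 and 16 in V-SVZ, with medians of −1.34 and −1.60. Lower calls on that scale made up 12374 of 17800 genes in cortex and 6742 of 17981 in V-SVZ. With the authors' scaling the list was called in no comparison by camera, with medians of −0.29, −0.22, −0.23 and −0.38 in that order and a mean of 0.08 between JKO regions. Monocyte genes were not called either (median 0.48 in V-SVZ by genotype, −0.75 on the homeostatic scale), with Itga4 (−1.20 ± 0.10) and Fn1 (−1.48 ± 0.25) down between WT regions and Vcan (−2.28 ± 0.32) down in V-SVZ by genotype.

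Genes that mark sex and strain were read as checks of the libraries. Xist, from the inactive X chromosome, stood at 775 to 1803 CPM and the Y-linked Ddx3y at 9.63 to 33.7 CPM, so transcripts of both sexes were present in all 9 libraries. The sex-linked list was called in no comparison, with a median of −0.61 (−1.84 on the homeostatic scale) in V-SVZ by genotype and of −0.05 (0.08 on the homeostatic scale) with a mean of 0.65 between WT regions. Nnt, which carries a deletion in C57BL/6J mice, was measured at 2.33 to 4.69 CPM in every library and was called by limma in no comparison. In JKO against WT cortex its log2 fold change was 0.89 ± 0.21 (2.49 ± 0.0940 to 4.25 ± 0.505 CPM, adjusted p = 0.0772) and −0.22 on the homeostatic scale. The authors' deposited table calls Nnt there (0.89, adjusted p = 0.00914). Cyfip2, which carries a variant in C57BL/6N mice, fell in JKO against WT V-SVZ (−1.36 ± 0.23, 122 ± 40.0 to 38.4 ± 6.63 CPM, SD, n = 2 and 2) and stood at −0.98 ± 0.26 in cortex without a call. The strain list was called in no comparison, with a median of 0.07 (−1.16 on the homeostatic scale) and a mean of −0.27 in V-SVZ by genotype. Of the neighbours of Pear1 on chromosome 3, Lrrc71, which overlaps the end of Pear1, rose between WT regions (2.18 ± 0.20, 5.51 ± 0.903 to 27.5 ± 5.43 CPM) while Pear1 fell. By genotype Lrrc71 stood at −2.80 ± 0.55 in cortex and −2.40 ± 0.48 in V-SVZ and Insrr at −2.13 ± 0.61 in cortex, none called, and Bcan fell in V-SVZ (−1.89 ± 0.31). The list of neighbours was called in no comparison, with medians of −0.11 (0.02 on the homeostatic scale) between WT regions, −0.07 (−0.07) between JKO regions, −0.12 (−1.22) in cortex and −0.02 (−1.25) in V-SVZ by genotype.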
